A study of Mus musculus with 14 samples.

How the data were processed

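Genomic DNA of clonal lines of 4T1, a mouse mammary carcinoma cell line, was bisulfite converted and sequenced genome-wide, per the labels' protocols. Bisulfite converts unmethylated cytosine and leaves methylated cytosine in place, so that the share of unconverted cytosines gives a methylation level. The labels describe 14 libraries, made in 2 rounds from each of 6 clones and from the parental line. Clones E and T were labelled intravasating, that is, able to enter the blood vessels. Clones I, K, L and P were labelled non-intravasating.

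The deposited values were fractions from 0 to 1, with 1 value per clone for each gene promoter and for each hypomethylated region (HMR, a stretch of the genome with low methylation). The values of the 2 rounds had no separate columns, and how the rounds were combined is not given in the sources used here. The parental line was not analysed here. Per the submitters' processing notes, the tools bedtools and DESeq and the build mm10 were used, with no role stated for either tool. The aligner, the promoter boundaries, the HMR caller and the way in which a level was averaged over a region are not given in the sources used here.

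HMR coordinates are printed as the deposited table gives them. On chromosome 7 the last HMR ended at 152.5 Mb and 379 HMRs ended past the last gene of GRCm38 (mm10), at 145.3 Mb. The HMR coordinates were therefore not in mm10, and their build was not established. Whether the starts count from 0 or 1 was not stated. For this reason HMRs were not assigned to genes, exons or introns. The promoter table carried gene names and no coordinates. Gene names were looked up in the RefSeq table of GRCm38.p6 for their chromosome only: 18885 of 20343 names matched by symbol, 1349 by synonym and 109 not at all.

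The promoter table held 22110 rows. Rows with the same gene and the same 6 levels, 145 in all, were counted once, which left 21965 promoters. The levels of 249 promoters were equal to those of another gene, and such genes cannot be told apart here. The HMR table held 101564 regions with a median length of 5054 bp. No counts or coverage came with either table, so the depth behind each level is unknown and no interval from counting error is given. Coverage minimums could not be applied. Between 25.7% and 36.9% of HMRs were at exactly 0 in a given clone, against 0.310% to 0.596% of promoters, and 18.67% of HMRs were at exactly 0 in all 6 clones. On chromosome Y, 13 of the 14 HMRs were at 0 in all 6 clones. A level of exactly 0 can be an unmethylated region or a region without a usable estimate, and the table does not tell these apart.

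Each clone was 1 replicate, giving 2 intravasating against 4 non-intravasating clones. The labels do not say that rounds were separate cultures. Levels were compared with limma 3.58.1 in R 4.3.3 (eBayes with a mean trend) and Benjamini-Hochberg adjustment, and a region was called at an adjusted p under 0.05. The design held a count model in reserve for methylated and unmethylated read counts, and it was not used since the tables hold levels alone. A region was termed separated when both intravasating clones lay above, or below, all 4 non-intravasating clones with a gap of at least 0.2 between the nearest clones. Mean levels per clone were compared by exact permutation over the 15 splits of 6 clones into 2 and 4, for which the smallest possible two-sided p is 0.0667. The distance between clones was the mean absolute difference of levels. Fixed gene lists, 21 in all, were tested on the mean promoter level per gene with limma camera at a preset correlation of 0.01 and with an estimated correlation. Separated regions on chromosome X were set against autosomes with Fisher's exact test, two-sided. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used for the rest.

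The tests, gene lists and alternatives were fixed before the data were examined. The alternatives were a logit scale with levels bounded at 0.01 and 0.99, an arcsine scale, no mean trend, clones centred on their median, regions with a range of at least 0.1, autosomes only, an adjusted p under 0.10, other gaps, and each clone left out. Genes were named by rule: in each direction up to 12 regions that were called and had no overlap between groups, by the difference of means, filled up from the separated regions by the gap. Serpine2 and Slpi were always named, as were members of the fixed lists that were called or separated, and up to 2 clone-specific promoters per clone (at least 0.5 from the median of the other 5 clones). Genes named from the gap of 0.1, from the range filter, as the ends of a gene list, or as standing apart in 1 clone were chosen after their values were seen.

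The limma step was tested on simulated levels with the mean and spread of each region and 200 regions changed by a known amount. For the 21965 promoters it called 0 changed promoters at a difference of 0.1, 30.5% at 0.2 and 90.5% at 0.4, with 10 unchanged promoters called beside the last. For the 101564 HMRs it called 0 at 0.1, 0 at 0.2 and 2.5% at 0.4, with 18 unchanged HMRs called beside the last. With no HMR changed, 25 were called. For the 50484 HMRs above 0 in all 6 clones it called 0 changed HMRs at 0.4. The mean estimated difference was 0.404 for HMRs changed by 0.4.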

Results

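DNA methylation was measured over gene promoters and HMRs in 6 clonal lines grown from single cells of 4T1, a mouse mammary carcinoma line that spreads from the mammary gland. The 6 clones came from a set of 23 that had been assessed as a pool for their capacity to enter the vasculature. Clones E and T were intravasating and clones I, K, L and P were not. Each group comparison therefore set 2 clones against 4, with 1 value per clone. The read depth behind the levels is unknown.

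The first comparison asked whether the intravasating clones differed in methylation over the genome as a whole. With 15 splits the exact permutation p cannot go below 0.0667, so this test could not pass at 0.05 and the values are given as they are. Mean promoter methylation was 0.391 ± 0.0192 (SD, n = 2) in the intravasating and 0.397 ± 0.0189 (SD, n = 4) in the non-intravasating clones, and the exact permutation test gave p = 0.867, two-sided. Clone L had the lowest mean promoter level, 0.369, followed by clone T at 0.377, while clones K, E, P and I lay between 0.402 and 0.412. Mean HMR methylation was 0.158 ± 0.0538 (SD, n = 2) in the intravasating and 0.148 ± 0.0276 (SD, n = 4) in the non-intravasating clones (exact permutation p = 0.80, two-sided). Clone E had the highest mean HMR level, 0.196, and clone T, at 0.120, had the second lowest after clone L at 0.108. The sign of both differences depended on single clones: without clone T the promoter difference was 0.00709, and without clone E the HMR difference was -0.0280.

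Promoter methylation was then compared gene by gene, the contrast stated in the study design. Promoters of Mup8, a gene of the major urinary protein family, and of Prb1, a proline-rich protein gene, were called higher in the intravasating clones, and no promoter was called lower. The Mup8 promoter was at 0.333 in clone E and 0.250 in clone T and was listed at 0 in all 4 other clones (limma adjusted p = 0.00415). These levels equal fractions of small whole numbers and may rest on few reads or sites. The Prb1 promoter was at 0.240 ± 0.00609 (SD, n = 2) against 0.0408 ± 0.0146 (SD, n = 4), with a limma adjusted p of 0.00415. The Prb1 levels also equal fractions of fairly small whole numbers and may rest on few reads or sites. The small SD of the intravasating clones therefore does not show that Prb1 was measured more precisely than Mup8. Over the alternatives the limma adjusted p was 4.48e-05 to 0.237 for Mup8 and 0.00321 to 0.453 for Prb1. Prb1 was not called on the logit scale (0.453), and neither was called without the mean trend (0.237 for both) or without clone L (0.0686 and 0.0625). The promoter of the X-linked microRNA gene Mir465 was separated without being called, at 0.512 and 0.522 in clones E and T against 0.182 to 0.263 in the others (limma adjusted p = 0.306). It was called after centring (0.0262) and among promoters with a range of at least 0.1 (0.00233), a filter that a separated promoter passes by construction. Over the alternatives its adjusted p was 0.00233 to 0.688. The Mir465 levels likewise equal fractions of fairly small whole numbers and may rest on few reads or sites. Mup8 and Mir465 were the only promoters separated by 0.2, whereas 43 were separated without clone E and 28 without clone T. Simulated levels with no change between the groups gave 4 separated promoters, but the simulated spread included any group difference and no clone-wide shifts.

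With the smaller gap of 0.1, 10 promoters were higher and 18 lower in both intravasating clones. Of these, limma called Mup8 and Prb1 over all promoters. Among promoters with a range of at least 0.1 it called 7 of them: Mup8, Prb1, Mir465, Olfr64 (adjusted p = 0.00369), Olfr180 (0.0110), Hunk (0.00118) and 2510009E07Rik (0.0422). Promoters with such a gap pass the range filter by construction. The filtered fit also called Gm14351 (limma adjusted p = 6.84e-05), which was at 1.00 in clone K, 0.250 in clone I and 0 in the others. Calls under this filter are therefore weak support. Olfr64 and Olfr180 were also called after centring (0.0262 for both). Over the alternatives the adjusted p went up to 0.966 for Olfr64 and to 1.0 for Olfr180, Hunk and 2510009E07Rik. Among the lower ones, Ncam2, a neural cell adhesion molecule gene, was at 0.524 and 0.537 in clones E and T against 0.759 ± 0.0337 (SD, n = 4) in the others (limma adjusted p = 0.337). Hunk, a protein kinase gene, had the largest difference of means in this set. Its promoter was at 0.268 in clone E and 0.0987 in clone T against 0.508 ± 0.0557 (SD, n = 4). The promoter of Pla1a, a phospholipase gene, was at 0.223 against 0.462 as group means, and 1 of the 3 promoters of Mgat1, a glycosyltransferase gene of N-glycan synthesis, at 0.223 against 0.448. The other two Mgat1 promoters were at 0.0136 against 0.0176 and at 0.188 against 0.129. Tshz2, a zinc finger gene, was at 0.652 against 0.786, and S100a14, a calcium-binding protein gene, at 0.602 against 0.746. Among the higher ones, the trypsin inhibitor gene Spink3 was at 0.474 against 0.30 and Gpr137b at 0.461 against 0.307. Receptor genes of smell and pheromone sensing stood on both sides: Olfr64, Olfr180, Olfr290 and Vmn1r115 were higher, and Olfr1294, Olfr502, Olfr1382, Vmn1r6 and Vmn2r54 were lower.

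**Figure D1:**
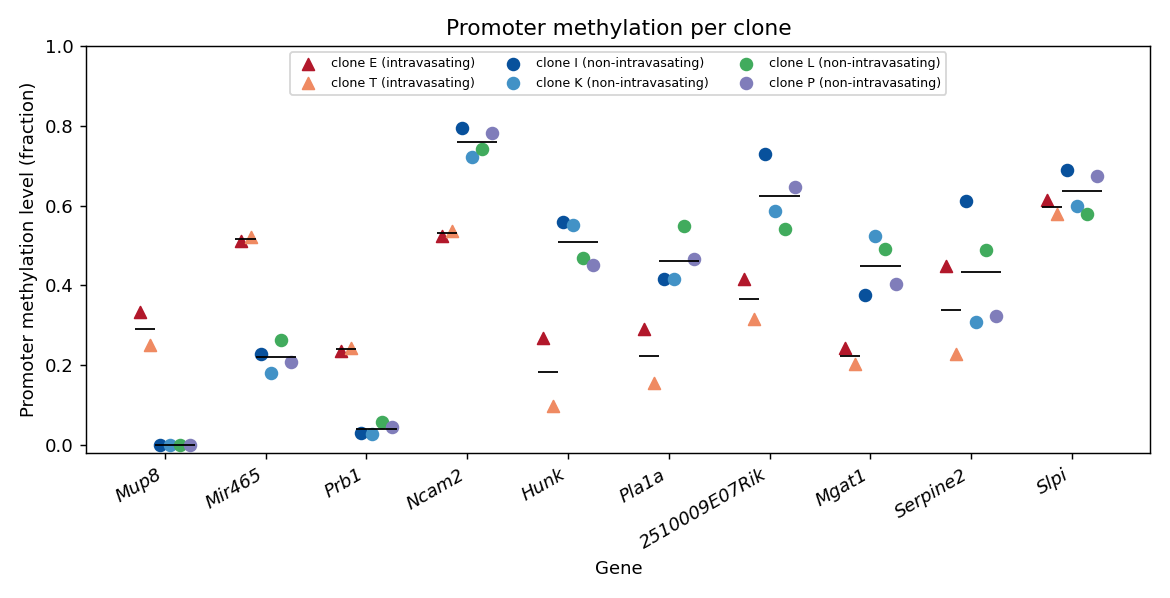
Promoter methylation level (fraction, vertical axis) of 10 genes in each of the 6 clones, with triangles for intravasating and circles for non-intravasating clones and bars for the group means. Mup8, Mir465 and Prb1 lay higher in clones E and T, and Ncam2, Hunk, Pla1a, 2510009E07Rik and 1 of the 3 Mgat1 promoters lower, while Serpine2 and Slpi overlapped between the groups.

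Serpine2, an inhibitor of serine proteases, and Slpi, the secretory leukocyte protease inhibitor, are the genes the study is known for, chosen on expression in these clones. Neither promoter passed the test. The Serpine2 promoter was at 0.449 in clone E and 0.229 in clone T, and at 0.611, 0.309, 0.489 and 0.323 in clones I, K, L and P. Its difference of -0.0938 had an unadjusted limma p of 0.358, and the sign changed without clone T (0.0162). The Slpi promoter was at 0.596 ± 0.0250 (SD, n = 2) against 0.636 ± 0.0542 (SD, n = 4), with an unadjusted limma p of 0.405.

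In all, limma called 2 of 21965 promoters, and 864 had an unadjusted p under 0.05. The groups did not overlap at 11.2% of promoters, where chance gives 13.3%. Without clone L no promoter was called (1691 with an unadjusted p under 0.05), without clone E 4 were called, and without the mean trend none was called (943 with an unadjusted p under 0.05). Among promoters with a range of at least 0.1, 25 were called, 11 higher and 14 lower. The groups overlapped at 12 of these 25, 1 of the 3 Wnt7b promoters among them, at 0.907 and 0.882 in clones E and T but 0.922 in clone I.

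HMRs called higher in the intravasating clones were mostly regions listed at 0 in every non-intravasating clone. limma called 162 of 101564 HMRs, 160 of them higher and 2 lower, and 3012 had an unadjusted p under 0.05. This direction was not particular to the intravasating pair. Other pairs set against the rest also had nearly all calls higher, such as 92 of 97 for T and L. All 4 non-intravasating clones were at exactly 0 in 159 of the 162. The differences were small, with a median absolute difference of 0.0746. The HMR with the largest difference lay on chromosome X from 10061686 to 10062241 and was at 0.667 in clone E and 0.750 in clone T. On chromosome 2, the HMRs from 97130204 to 97135639 and from 173595301 to 173595966 were both at 0.50 in clones E and T. All 3 were listed at 0 in the other 4 clones. Their levels in clones E and T equal fractions of small whole numbers and may rest on few reads or sites. The call on X was lost on the logit scale (limma adjusted p = 0.199, 1.78e-08 to 0.199 over the alternatives). Both calls on chromosome 2 were lost on the logit scale (0.320), on the arcsine scale (0.0748) and without any 1 of clones I, K, L and P (0.0617 to 0.0780), with a range of 2.95e-06 to 0.320. The 2 HMRs called lower were on chromosome 14 from 28978345 to 28986764, listed at 0 in clones E and T against 0.0758 ± 0.00566 (SD, n = 4), and on chromosome 9 from 48444551 to 48446627, listed at 0 against 0.0328 ± 0.00104 (SD, n = 4). After centring neither was called (0.969 for both), and the range over the alternatives was 0.0295 to 1.0 on chromosome 14 and 0.000558 to 0.969 on chromosome 9. The call on chromosome 14 was also lost on both other scales (1.0 logit, 0.470 arcsine) and without clone E (0.347), I (0.0994), K (0.0989) or P (0.112).

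Separated HMRs, with a gap of at least 0.2, numbered 71, of which 44 were higher and 27 lower in the intravasating clones. Without clone T they numbered 2316 and without clone E 635. In 26 of the 44 all 4 non-intravasating clones were at exactly 0. The widest lower gap was on chromosome 2 from 136935157 to 136936383, at 0.0588 in clone E and 0 in clone T against 0.622 ± 0.109 (SD, n = 4). On chromosome 16, the HMR from 90385687 to 90387643 was listed at 0 in clones E and T against 0.507 ± 0.0705 (SD, n = 4), and the one from 4474848 to 4475461 was listed at 0 against 0.517 ± 0.111 (SD, n = 4). None of these 3 was called by limma over all HMRs. All were called among HMRs with a range of at least 0.1 (adjusted p = 0.0141 for the one on chromosome 2 and 0.0103 for both on chromosome 16). Separated HMRs pass this range filter by construction, so these calls are weak support. Both on chromosome 16 were also called on the logit scale (0.00381 and 0.0131) and the arcsine scale (0.00860 and 0.0392), and the first after centring (0.0447). The logit scale sets their levels of 0 in clones E and T to 0.01, so the logit calls are weak support too. Such zeros may be regions without a usable estimate. Levels in the other clones, such as 0.50 in clone L for both, equal fractions of small whole numbers and may rest on few reads or sites. Over the alternatives the adjusted p went up to 0.872 on chromosome 2 and to 0.276 and 0.725 on chromosome 16. Simulated levels with no change between the groups gave 104 separated HMRs over the 101564 regions. The simulated spread included any group difference and no clone-wide shifts, so 104 is no strict reference for 71. The limma calls numbered 3 among HMRs with a mean level of at least 0.1, 0 among those above 0 in all 6 clones (1532 with an unadjusted p under 0.05), and 6 after centring each clone. Both filters leave out HMRs at 0 in 4 clones by construction, the first unless their intravasating mean is at least 0.3. The calls numbered 3146 without clone T and 1142 without clone E.

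The likeness of the 2 intravasating clones was compared with that of other pairs. Clones E and T were not among the closest pairs. Over promoters their distance was 0.0461, rank 8 of the 15 pairs from the closest, and the closest pair was K and P, both non-intravasating, at 0.0392. Over HMRs the E and T distance was 0.0955, rank 14 of 15, and the closest pair was T and L at 0.0639. Clone L had the largest mean promoter distance to the other clones, 0.0536, and clone E the largest mean HMR distance, 0.0886. By 1 minus Pearson r over HMRs, E and T ranked 9 of 15, T and L ranked 14, and E and I were the closest pair. Clones T and L had the lowest mean HMR levels, which a mean absolute difference takes in and a correlation does not.

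**Figure D2:**
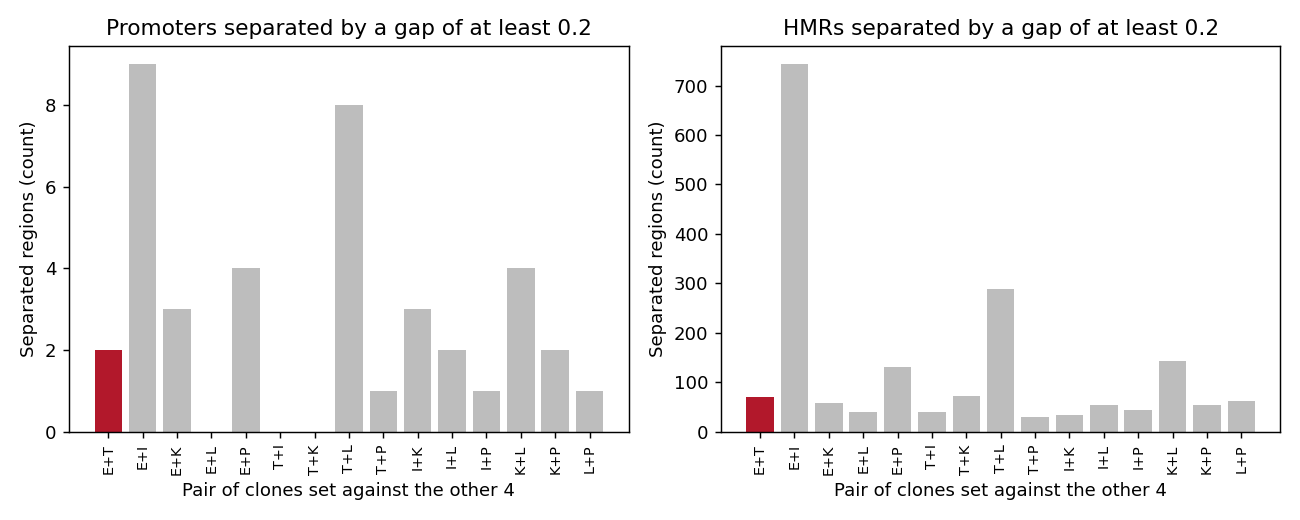
Number of promoters (left) and HMRs (right) separated by a gap of at least 0.2 when each pair of clones (horizontal axis) is set against the other 4, with the intravasating pair in red. The intravasating pair gave 2 promoters and 71 HMRs, and the pair E and I gave the most, 9 and 743.

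Gene lists were used to ask whether promoters of related genes shifted together. No list did so by camera: the smallest adjusted p among the 21 lists was 0.175, and adjusted p = 0.996 with an estimated correlation. No member of any list was called, over all genes or adjusted over the list alone. Epithelial genes had a mean level of 0.299 ± 0.0218 (SD, n = 2) in the intravasating and 0.291 ± 0.0179 (SD, n = 4) in the non-intravasating clones, and mesenchymal genes 0.554 ± 0.00101 against 0.571 ± 0.0158. Of the 37 mesenchymal genes 26 had a lower mean in the intravasating clones, and of the 33 epithelial genes 20 had a higher one. Lower means also prevailed in lists unrelated to these, with 71 of 86 developmental transcription factors, 30 of 37 HOX genes and 26 of 33 imprinted genes. The promoter of the intermediate filament gene Vim was nearly free of methylation in all clones, at 0.00643 ± 0.00588 (SD, n = 6), whereas those of Zeb1, a repressor of epithelial genes, and Cdh2, the N-cadherin gene, were at 0.946 ± 0.0136 and 0.932 ± 0.0167 (SD, n = 6).

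Coagulation and fibrinolysis genes, 25 in all, were at 0.417 in the intravasating and 0.429 in the non-intravasating clones as group means. Over the 6 clones they ranged from S100a10 at 0.00636 to the antithrombin gene Serpinc1 at 0.894. The urokinase receptor gene Plaur was at 0.0135. The 35 matrix proteases and inhibitors were at 0.450 against 0.459, the 31 mammary luminal and basal genes at 0.438 against 0.450, and the 49 adhesion genes at 0.481 against 0.484. The 39 endothelial and angiogenesis genes were at 0.527 against 0.533. The 33 cytokine and chemokine genes were at 0.482 against 0.502, and Csf3, the gene of a granulocyte growth factor, was at 0.0130 over the 6 clones. Antigen presentation and interferon genes were at 0.254 against 0.272, with 28 of 36 lower in the intravasating clones. This list passed only without clone I (camera adjusted p = 0.0298, preset correlation), not at the estimated correlation (0.999), and without clone L its direction turned to higher (unadjusted camera p = 0.904). Its promoter of Nlrc5, the activator of class I antigen presentation genes, was at 0.831.

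Highly methylated lists were HOX genes (0.679 against 0.691), imprinted genes (0.683 against 0.698), developmental transcription factors (0.761 against 0.774) and germline genes (0.785 against 0.790). Clustered protocadherins were at 0.657 against 0.665. Of the markers of other cell types, leukocyte genes were at 0.629 against 0.633 and fibroblast genes at 0.655 against 0.657. Housekeeping genes were low at 0.0910 against 0.0921, DNA methylation machinery genes were at 0.226 against 0.222, tumour suppressor genes at 0.536 against 0.554, and the 1380 olfactory and vomeronasal receptor genes at 0.352 against 0.354. The study genes Serpine2 and Slpi as a list were at 0.468 against 0.534, which is not independent evidence since the study chose them. Without clone L, 6 lists passed camera at the preset correlation: HOX, developmental transcription factors, imprinted, germline and tumour suppressor genes lower, and DNA methylation machinery genes higher. At the estimated correlation none of these passed without clone L (camera adjusted p = 0.801, smallest unadjusted p of the 6 lists 0.130).

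Separated regions were counted on chromosome X, since 4T1 came from a female mouse. HMRs on X were separated more often than those on autosomes: 18 of 4301 against 53 of 97247, an odds ratio of 7.71 (Fisher's exact p = 6.7e-10, two-sided, adjusted p = 2.01e-09 over 6 such tests). This p takes HMRs as independent, which neighbouring HMRs of the same clones are not. Every other pair of clones set against the rest also gave a larger share of separated HMRs on X, with odds ratios from 2.63 for T and L to 33.9 for T and K, so the excess was not particular to the intravasating pair. Of the HMRs on X before 80 Mb, 58.6% to 88.4% were at exactly 0 in a given clone, against 24.8% to 34.8% on autosomes. All 18 were higher in the intravasating clones. Of the separated promoters 1 was on X and 1 on an autosome (Fisher's exact p = 0.0821). The mean level of X HMRs was 0.225 in clone E and 0.0654 in clone T, against 0.134 in clone I, 0.0963 in clone P, 0.0604 in clone L and 0.0499 in clone K (exact permutation p = 0.40, two-sided).

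**Figure D3:**
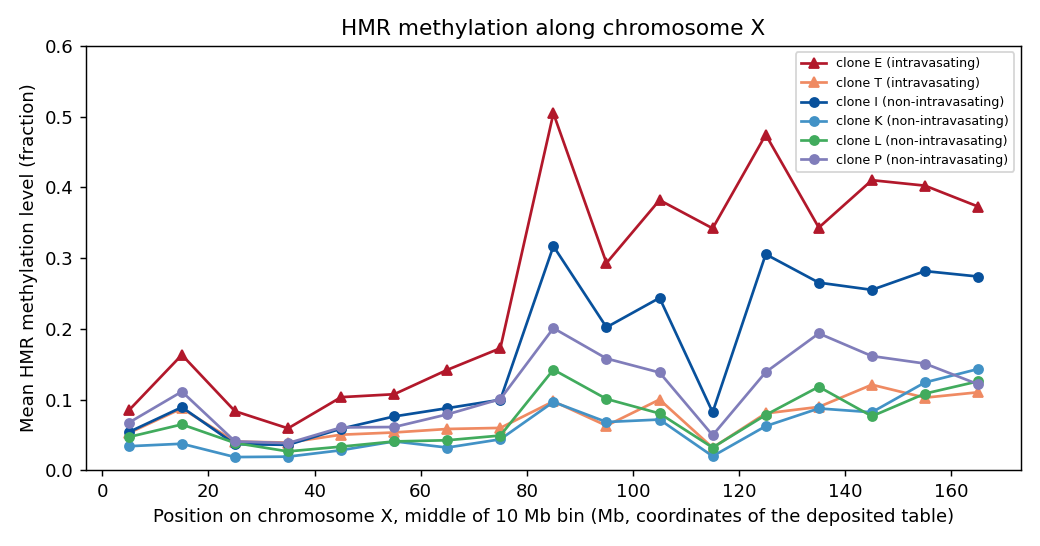
Mean HMR methylation level (fraction, vertical axis) in 10 Mb bins along chromosome X in the coordinates of the deposited table (Mb, horizontal axis), 1 line per clone, with triangles for the intravasating clones. From 80 Mb onwards clone E had a mean of 0.384 and clone I of 0.229, and the other clones lay between 0.0754 and 0.137.

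Clone-specific regions, at least 0.5 from the median of the other 5 clones, were found in every clone. Among promoters they numbered 6 in clone E, 4 in T, 4 in I, 8 in K, 3 in L and 3 in P. The promoter of Vmn2r96, a pheromone receptor gene, was at 0.667 in clone E and at most 0.286 elsewhere. That of Gm16445 was at 0.115 in clone T and at least 0.451 elsewhere. Magea1, a gene of the germline-expressed MAGE family, was at 0.333 in clone L against 0.727 to 1.00 in the others, and Gm14351 was at 1.00 in clone K against at most 0.250. Several of these levels, such as 0.667, 0.333 and 0.250, equal fractions of small whole numbers. They may rest on few reads or sites, whose number is unknown. Zscan4f, a gene of early embryos and embryonic stem cells, ranged from 0 in clone I to 0.857 in clone K and was named for 4 clones. In clones L (0.143) and P (0.833) it met the rule but lay within the range of the other clones. Among HMRs, clone E had the most, 596, of which 574 were higher, and clone P the fewest, 51. The planned comparison with the parental line was not analysed here.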

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

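Of 57 per-clone values checked for a non-intravasating clone far from the other 3, 7 were marked, and chance marks about 1 in 20. Clone L lay below the other 3 in 18 of the 21 gene lists, and in 6 of these far enough to be marked. In leukocyte genes clone L was at 0.572 and the others at 0.653 to 0.655 (gap over range 0.978). In clustered protocadherins it was at 0.610 against 0.681 to 0.687 (0.923), and in endothelial and angiogenesis genes at 0.509 against 0.539 to 0.544 (0.865). Adhesion genes were at 0.461 in clone L against 0.489 to 0.494 (0.864). Developmental transcription factors were at 0.740 against 0.782 to 0.791 (0.834), and olfactory and vomeronasal receptors at 0.292 against 0.368 to 0.383 (0.831). These lists share the low overall promoter level of clone L, 0.369. The promoter of Vmn2r54 was at 0.545 in clone K against 0.442 to 0.448 in clones I, L and P (0.938).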

How the results depend on the processing

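The coverage minimums of 5 and 20 were not run, since the tables hold no coverage. No paired analysis was possible because the columns carry no round. The filters on HMRs at a mean level of at least 0.1 or above 0 in all 6 clones, the run with duplicate promoter rows kept, and camera at an estimated correlation with a clone left out, were chosen after seeing the data. Where a count or sign moved, the cause was not tested, except that a filter tests fewer regions and a left-out clone leaves fewer samples. Where clone E or T was left out, the lone intravasating clone was assumed to vary like the others.

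Called promoters, 2 by limma, numbered 0 without the mean trend, 5 after centring and 25 with a range of at least 0.1, and 0 to 4 with a clone left out. Called HMRs, 162, numbered 273 on the logit scale, 319 on the arcsine scale, 6 after centring, 75 with a range of at least 0.1, 3 with a mean level of at least 0.1 and 0 above 0 in all 6 clones, and 103 to 3146 with a clone left out. Separated promoters, 2, numbered 28 at a gap of 0.1, 0 at 0.3 and 1 on autosomes, and 3 to 43 with a clone left out. Separated HMRs, 71, numbered 613 at a gap of 0.1, 10 at 0.3 and 24 above 0 in all 6 clones, and 108 to 2316 with a clone left out.

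The difference in mean promoter level, -0.00646, was -0.0200 to 0.00709 with a clone left out, positive without clone T. That in mean HMR level, 0.00998, was -0.0280 to 0.0480, negative without clone E and, at -0.00317, without clone L. The Serpine2 difference was -0.204 to 0.0162 with a clone left out, positive without clone T. The E and T rank over HMRs, 14, was 9 by 1 minus Pearson r. Lists past camera, 0, numbered 0 to 6 with a clone left out, and 0 at the estimated correlation (smallest unadjusted p 0.0764). The X odds ratio for promoters was 0.879 at a gap of 0.1, and that for HMRs, 5.65 at a gap of 0.3, had a Fisher's exact p of 0.0644. At a gap of 0.3 no promoter was left to compare.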

Other observations

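Several promoters stood apart in 1 clone by a gap of at least 0.2 to the nearest other clone, a set chosen after the values were seen. In clone T the promoter of Vgll3, a transcription cofactor gene, was at 0.0816 against 0.424 to 0.748, and that of Ecm2, an extracellular matrix protein gene, at 0.490 against 0.834 ± 0.0182 (SD, n = 5). Sfrp1, a Wnt antagonist gene, was at 0.238 in clone T and at least 0.462 elsewhere. In clone L, Mir200c, a microRNA gene of epithelial cells, was at 0.0409 and from 0.286 to 0.683 elsewhere, Rab25, an epithelial GTPase gene, at 0.339 and at least 0.540 elsewhere, and Sele, the E-selectin gene, at 0.419 against 0.682 ± 0.0252. Nr4a1, a nuclear receptor gene, was at 0.644 in clone L against 0.254 ± 0.0546, and Nupr1, a stress response gene, at 0.267 against 0.0190 ± 0.0161.

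By a gap of 0.2 to the nearest clone, clone E had 20 promoters above all others and 1 below, and clone T had 4 above and 27 below. Clone L had 7 above and 30 below, clone I 13 and 4, clone K 14 and 3, and clone P 10 and 2. Receptor genes of smell and pheromone sensing had wide ranges between clones more often than other genes: 40.2% of 1382 such promoters and 8.61% of 20583 others had a range of at least 0.2 (Fisher's exact p = 9.8e-200, odds ratio 7.15, across promoters, which are not independent). Among promoters with a mean level of 0.2 to 0.8, a comparison chosen after the values were seen, it was 45.5% of 1024 and 17.7% of 9279. Counting error was not separated from differences between clones, since the depth is unknown.

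The tests that follow were chosen after the results were seen for the separated promoters and HMRs, for clone E over the whole genome, intravasating capacity and X-linked promoters on distal X, and for whole-chromosome levels and chromosome labels on chromosome 16. The others were set before the result they measure was seen.

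Whether the HMRs called higher in the intravasating clones come from levels of exactly 0 in the non-intravasating clones was not decided. Of the 162 calls, 3 were left among HMRs with a mean level of at least 0.1, but 156 of the calls, at 0 in 4 clones, differed by too little to pass that filter. The differences were under 0.1 in 116 of the 162. In the other splits, too, nearly all called HMRs were higher in the pair, such as 421 of 422 for E and I and 92 of 97 for T and L. The higher direction of the calls therefore says nothing particular about the intravasating clones. 4T1 came from a female mouse, and 13 of the 14 HMRs on chromosome Y were listed at 0 in all 6 clones. Zeros can therefore stand for regions without data. Whether the zeros behind the calls are of this kind or are unmethylated regions stays open.

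A share under 0.05 cannot be reached with 15 splits: 4 splits gave as many called HMRs, with 162 in the real split and 422 in the highest other, E and I. For called promoters 3 splits gave as many, with 2 and 8. For separated promoters it was 9 splits, with 2 and 9, and for separated HMRs 6 splits, with 71 and 743. For the odds ratio of separated HMRs on X against autosomes it was 6 splits, with 7.71 and 33.9. The counts partly follow the overall level: E and I had the highest mean HMR levels and 731 of their 743 separated HMRs were higher, T and L the lowest and 10 of 289 were higher. After centring each clone, chosen for these pairs after the counts were seen, E and I still gave 450 separated HMRs, T and L 115, and the real pair 59. Of these 450, 422 were higher, so taking off the median did not remove the one-sidedness. Of the 743 before centring, 314 were on X, where E and I had the highest mean HMR levels. The count for E and I, several times the real one, shows differences between clones that do not follow the groups. Whether they go beyond the mean level of each clone was not decided.

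HMR levels on distal X, from 80 Mb in the deposited coordinates, a boundary placed after seeing the levels, were higher in clone E than in the other 5 clones, at 0.384 against a mean of 0.122. Levels of exactly 0 in the other clones do not account for it, since among the 219 distal X HMRs above 0 in all 6 clones, clone E still exceeded the highest other clone by 0.114. The excess of clone E on distal X was 0.212 above that on autosomes. Distal X was chosen for this excess, so the comparison cannot decide on a higher level of clone E over the whole genome. The choice did not fix the order of clone T among the other clones. The difference of clone T from clone I was -0.147 on distal X and -0.0518 on autosomes. From the mean of the non-intravasating clones, clone T differed by -0.0504 on distal X and -0.0284 on autosomes. This argues against a rise on distal X shared by both intravasating clones. It rests on clone T alone, whose low HMR level was not taken off. The excess was not limited to X: with the median over bins taken off each clone, clone E stood 0.121 to 0.153 above the mean of the clones in 5 of 254 autosomal bins of 10 Mb and 0.108 to 0.247 in 9 of 17 X bins, while clone K stood 0.1 to 0.134 below in 5 of these X bins and clone L 0.125 below in 1 autosomal bin. Of 180 X promoters under 0.1 in the other clones, 1.67% were at least 0.1 higher in clone E, against 1.68% of 179 for clone P. This argues against many promoters over the whole of X that were methylated in clone E alone, as on an inactive X. It cannot decide for distal X, since the promoters had no coordinates, nor for an inactive X shared with another clone. A different copy number or parental origin of distal X was not tested.

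Of 17 promoters with a chromosome that were lower by a gap of 0.1 in the intravasating clones, 5 were on chromosome 16: Ncam2, Hunk, Pla1a, 2510009E07Rik and 4930451C15Rik. Fisher's exact test gave an adjusted p of 0.00544 over chromosomes and directions (odds ratio 12.9), which argues against chance over the chromosome labels if promoters are independent. The median promoter difference on chromosome 16 was 0.00113 above that of the other autosomes (bootstrap SE 0.00134). This argues against an even lowering of most promoters there. It cannot exclude a lower level in the variable part of the chromosome, since 56.2% of all promoters had a range under 0.1. Among the 15 splits, 3 gave a chromosome with as small a Fisher p, too few splits for a share under 0.05, with 0.000136 for the real one and 4.31e-05 for the lowest other, T and L. Of the 27 separated lower HMRs 5 were also on chromosome 16 (odds ratio 6.66, Fisher's exact p = 0.00173, unadjusted, HMRs taken as independent). The chromosome was chosen from the promoters, the clones are the same, and HMRs were not checked for overlap with these promoters. The HMR count is therefore not independent support. No test here decides between intravasating capacity and other differences between these clones.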
